A study of Mus musculus with 8 samples.

How the data were processed

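Hepatic stellate cells, the vitamin A-storing mesenchymal cells of the liver, were profiled by RNA sequencing, per the labels after isolation from livers of male mice with diet-induced steatohepatitis (MASH). The source of the cells is given as the labels state it and was not checked, because no gene of the list for stellate cell identity is in the rows shared by the tables. Per the labels, Western diet feeding (21% fat, 20% protein, 50% carbohydrate) began at 4 weeks of age and lasted 20 weeks, and livers were taken in week 24. The genotypes compared were a stellate cell-specific knockout of AREL1 (AREL1HSC-KO, called KO below) and the floxed control (AREL1fl/fl, called fl/fl), with 4 libraries each. Libraries were assigned to groups by their titles. In 3 of the 4 KO samples the genotype field carries another digit in the gene name than the title does, and the title was followed. AREL1 is an E3 ubiquitin ligase known for opposing apoptosis. The labels do not say whether each library came from a separate mouse, so p-values measure the spread between these libraries, which may be technical.

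Per the labels' protocols, livers were digested with pronase and collagenase, parenchymal cells were pelleted at low speed, stellate cells were collected from an OptiPrep density gradient, and poly(A) libraries were made with an Illumina stranded mRNA kit. The authors deposited 1 table of whole-number read counts per gene for each library, in the layout of the STAR gene counter, with 4 summary values (unmapped, multimapping, no feature, ambiguous) above the gene rows and 3 count columns for either strand, the forward strand and the reverse strand. The submitters' processing notes name fastp, STAR 2.7.10a and DESeq2 1.38.0, and both GRCm38 and GRCm39. The annotation release is not given in the sources used here, and no coordinates are printed for that reason.

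The tables as used here hold 1933 to 1943 gene rows, and an incomplete last line was left out. The 1933 gene rows that the 8 tables share were analysed. Of these, 1830 had a symbol in GENCODE M21 (GRCm38, used only for symbols, for chromosomes and for which genes overlap) and 103 did not. The 1830 rows all lie on chromosome 1 in that annotation, and they include 627 (51.9%) of its 1208 protein-coding genes there. Genes on other chromosomes, Arel1 on chromosome 12 among them, were not analysed here, so the knockout itself was not checked and the results describe part of 1 chromosome.

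The sum over these rows is 3.20% to 3.28% of a library and is not its depth. The library total was therefore derived from the summary counts. Reads over features of 1 strand only equal the no-feature reads of the forward and reverse columns minus 2 times those of the either-strand column, and subtracting the ambiguous reads of both strand columns gives a lower limit for the gene-assigned reads. The upper limit lay 2.51% to 2.65% higher. The lower limit, 17619387 to 25165289 reads per library, was used as the library size. The kit is named as stranded, but the reverse-to-forward ratio of reads was 0.985 to 1.02, far from the ratio of 4 set as the minimum for using a strand column, so the either-strand counts were used. Reads on exons of 2 overlapping genes are then counted as ambiguous and for neither gene.

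Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept with filterByExpr (420 of 1933), scaled with TMM, and tested with the quasi-likelihood F test (robust empirical Bayes), with Benjamini-Hochberg adjustment over the 420 genes and a threshold of 0.05. Levels are read counts scaled as CPM to the TMM-adjusted library total, as mean ± SD over 4 libraries. The SE of a log2 fold change was taken from its F statistic. Positive values are higher in KO. Data were simulated for these 420 genes with 200 changed, as many raised as lowered, and each count drawn independently. The test recovered 48% of 1.1-fold, 74% of 1.2-fold, 96% of 1.5-fold and 96% of 2-fold changes, and called 1 of 220 unchanged genes. A shift shared by many genes of a library was not simulated. A chi-square test of counts between libraries showed that no pair agreed within sampling noise (largest p = 1.96e-06 within KO and 5.15e-07 within fl/fl), so none was treated as a library deposited 2 times. This test cannot show that the libraries come from separate animals. Shares of reads were compared with two-sided exact permutation tests, for which 4 against 4 cannot give a p below 0.0286.

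Before the data were examined, the design, the alternatives, 33 lists of genes for stellate cell and liver programmes and 11 lists of markers of other cell types were fixed. Of the 904 genes listed, 25 were in the rows and 23 were kept. No list had the 5 kept genes set as the minimum for camera, a competitive gene set test, so list members are reported one by one. The rule for named genes was also fixed then. It takes the 10 highest and 10 lowest log2 fold changes among genes with adjusted p under 0.05, a mean of at least 5 CPM, no overlap between the groups' libraries, and a symbol that is not a predicted or clone name (51 higher and 60 lower genes were eligible). It adds 13 fixed genes, of which only Col3a1 was in the rows, and members of the fixed lists. Some genes that the rule takes are not reported here. Alternatives were other scalings, DESeq2 1.42.0, limma 3.58.1 (voom with quality weights), other filters, thresholds and count columns, each library left out, the replicate number as a block, and thinning to equal library totals. The library-totals, strand-column and thinning alternatives were added after the data had been examined. The covariates planned from hepatocyte, macrophage and endothelial genes were not run, because the rows hold no gene of those fixed lists.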

Results

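The data comprised 8 libraries labelled as stellate cells from mice on Western diet, 4 fl/fl and 4 KO. Gene-assigned reads numbered 17619387 to 19663030 in the fl/fl libraries and 19271004 to 25165289 in the KO libraries. The shared chromosome 1 rows held 563706 to 637282 reads per fl/fl library and 626250 to 826127 per KO library. The most abundant of these genes were Ncl, the nucleolar protein nucleolin (1968 ± 47.9 CPM in fl/fl, SD, n = 4), Ptma, prothymosin alpha (1477 ± 22.5 CPM), and Hspd1, the mitochondrial chaperonin HSP60 (1451 ± 44 CPM). The interstitial collagen genes Col5a2 and Col3a1 stood at 673 ± 6.82 and 485.2 ± 16.3 CPM. Libraries of 1 group differed little on average, with a biological coefficient of variation of 2.53% over the 420 genes kept. Replicate 4 of fl/fl stood apart from the other fl/fl libraries, with a chi-square of 3.2 to 3.32 per degree of freedom. Among those others it was 1.36 to 1.8.

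The comparison of KO with fl/fl asks what loss of AREL1 in stellate cells changes in their transcriptome during steatohepatitis. Arel1 itself was not analysed here, so the labels were not checked on the targeted gene. Of 420 genes, 158 (37.6%) changed, 77 higher and 81 lower in KO (edgeR quasi-likelihood test, adjusted p under 0.05). The E3 ubiquitin ligase gene Neurl3 rose 3.04-fold and the heparan sulfatase gene Sulf1 1.74-fold, while the aldehyde oxidase gene Aox1 fell by 77.3%, the matrix gene Dpt by 63.9% and the collagen gene Col6a3 by 39.7%. The median absolute log2 fold change of the changed genes was 0.194, and 8 genes changed at least 2-fold. The 3 higher were Neurl3, Ccl20 and the predicted gene Gm29216, and the 5 lower were Aox1, Gpr35, Dpt, Tmeff2 and Gm28800. Gpr35, Tmeff2 and the predicted genes fall outside the rule for named genes and were picked out after their values were seen. Gpr35 lay at a very low level, 1.03 ± 0.108 CPM in fl/fl and 0.2684 ± 0.12 CPM in KO. Gm28800 overlaps Zranb3 and Tmeff2 overlaps Gm28322 in the annotation used for symbols, so their counts are uncertain without strand. The groups did not overlap in 132 genes (31.4%), where chance gives 2.86% for 4 against 4. The split of 48.7% higher became 60.6% with library totals alone and 69.8% with upper-quartile scaling.

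**Figure D1:**
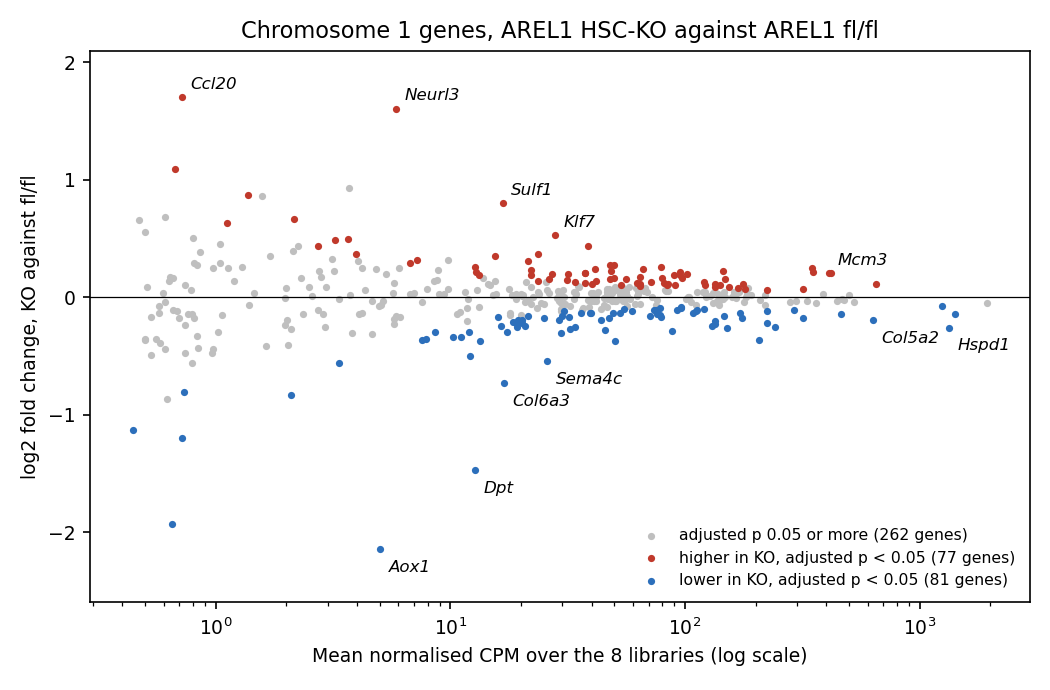
Log2 fold change of KO against fl/fl for each of the 420 chromosome 1 genes kept, against its mean normalised CPM over the 8 libraries on a log axis. Colours mark the 77 genes that were higher and the 81 that were lower at adjusted p under 0.05; Neurl3, Sulf1, Dpt and Aox1 stand apart among genes of moderate level.

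Among the 10 most increased genes, Neurl3 (ENSMUSG00000047180), a RING-type E3 ubiquitin ligase, rose 3.04-fold, from 2.902 ± 1.03 CPM in fl/fl to 8.814 ± 0.709 CPM in KO (SD, n = 4; log2 fold change 1.61, SE 0.15, edgeR adjusted p = 2.76e-08). Sulf1 (ENSMUSG00000016918), an extracellular sulfatase that trims heparan sulfate, rose 1.74-fold from 12.21 ± 2.45 to 21.24 ± 0.288 CPM (adjusted p = 2.54e-07). The transcription factor gene Klf7 rose 1.45-fold from 22.89 ± 2.49 to 33.04 ± 0.847 CPM (adjusted p = 2.56e-08). Atp1b1, a subunit of the sodium pump, rose 1.35-fold from 32.85 ± 1.62 to 44.37 ± 1.5 CPM. Dyrk3, Ap1s3, Wdfy1, Cnst and Mettl13 rose by 1.28-, 1.24-, 1.24-, 1.21- and 1.21-fold. In the annotation used for symbols, Atp1b1 overlaps Nme7, Wdfy1 overlaps Mrpl44 and Klf7 overlaps Gm26649. The counts of these genes are therefore uncertain without strand. Their calls held with either strand column, but reads fell on both strands about equally, so this does not settle the overlap. The call for Ap1s3 was lost when forward-strand counts were used (log2 fold change 0.098, adjusted p = 0.667, with a range of 0.00141 to 0.667 over the alternatives), and with reverse-strand counts its log2 fold change was 0.52.

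Among the 10 most decreased genes, Aox1 (ENSMUSG00000063558), an aldehyde oxidase, fell from 8.206 ± 1.64 CPM in fl/fl to 1.835 ± 0.291 CPM in KO (SD, n = 4; log2 fold change -2.14, SE 0.16, edgeR adjusted p = 3.23e-10). Dpt (ENSMUSG00000026574), which encodes the matrix protein dermatopontin, fell by 63.9% from 18.75 ± 2.78 to 6.762 ± 0.0922 CPM (log2 fold change -1.47, SE 0.094, adjusted p = 4.21e-11). Col6a3 (ENSMUSG00000048126), a chain of the microfibrillar collagen VI, fell by 39.7% from 21.19 ± 2.92 to 12.79 ± 0.236 CPM (adjusted p = 1.03e-07). The semaphorin gene Sema4c fell by 31.3% from 30.73 ± 1.26 to 21.13 ± 0.439 CPM. Mr1, which presents microbial metabolites to T cells, fell by 23.0%, and Qsox1, a secreted enzyme that forms disulfide bonds, fell by 22.9%. Prdx6, a peroxiredoxin, fell by 22.5% from 232.7 ± 17.2 to 180.5 ± 3.31 CPM. Per2, a component of the circadian clock, fell by 22.0%, and Sec16b, a protein of endoplasmic reticulum exit sites, by 21.1%. Dpt overlaps Gm32569 and Sec16b overlaps Gm15486. On the other strand, Sema4c overlaps D430040D24Rik and Qsox1 overlaps 1 gene. Their calls held with either strand column, which does not settle the overlap either. The call for Per2 was lost with reverse-strand counts (adjusted p = 0.0804, with a range of 8.32e-05 to 0.0804 over the alternatives).

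**Figure D2:**
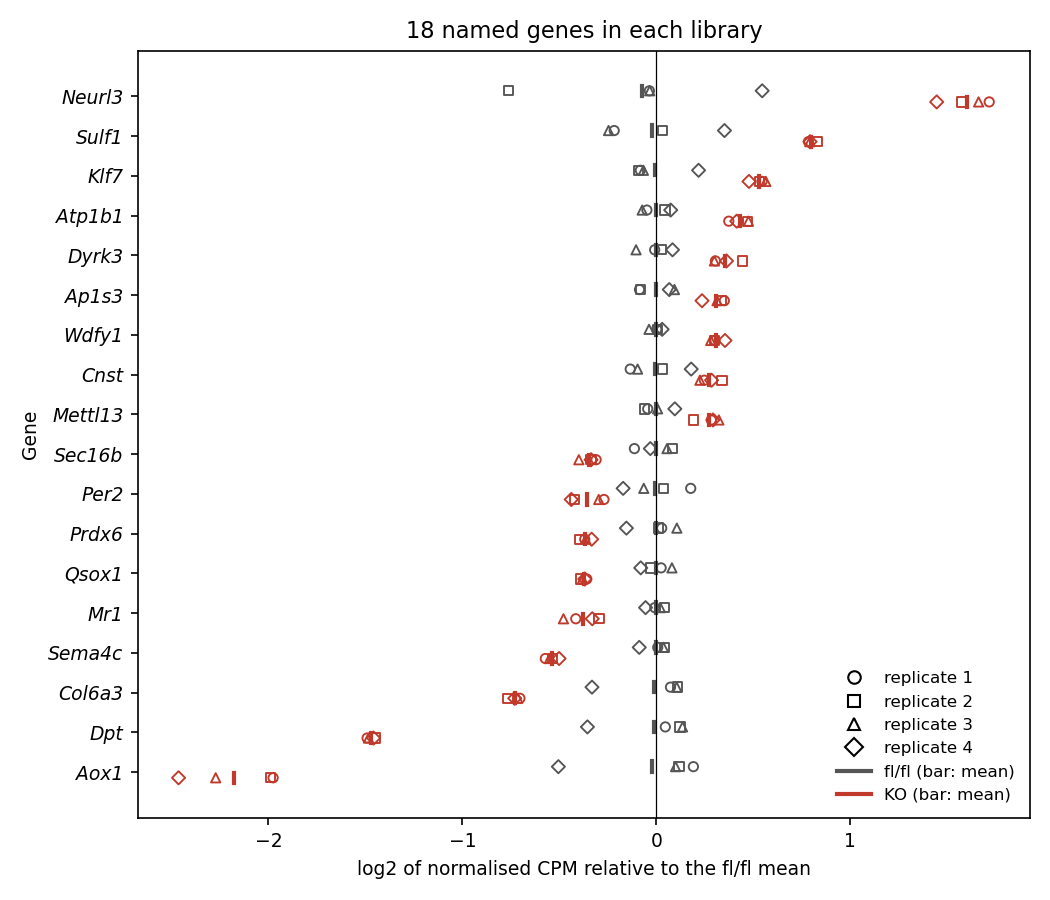
Level of 18 of the named genes in each of the 8 libraries, as log2 of normalised CPM relative to the fl/fl mean; symbols mark the replicate, colours the group and bars the mean of the 4 log2 values. The KO and fl/fl libraries do not overlap in any of these genes, which was a condition for naming them, and fl/fl replicate 4 lies on the KO side of the other fl/fl libraries in genes such as Klf7, Col6a3 and Aox1.

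In the gene lists fixed in advance, the 3 interstitial collagens present all fell. Col6a3 is given above. Col5a2 fell by 12.4%, from 673 ± 6.82 to 589.5 ± 5.02 CPM (edgeR adjusted p = 2.56e-08, n = 4 per group). Col3a1, a main fibrillar collagen of scar tissue, fell by 9.52%, from 485.2 ± 16.3 to 439.1 ± 0.801 CPM (log2 fold change -0.14, edgeR adjusted p = 2.04e-05). With upper-quartile scaling the log2 fold change of Col3a1 was -0.093 (adjusted p = 0.0073, the highest of the alternatives, which began at 1.31e-13). Dpt, the only gene of the matrix glycoprotein list in the rows, fell as well. The only gene of the basement membrane list, the laminin chain Lamc1, went the other way and rose by 18.5% from 317.9 ± 13.1 to 376.6 ± 8.27 CPM (edgeR adjusted p = 2.58e-08). Of 14 listed collagens only these 3 were in the rows, so the count describes them and not the list. In fl/fl replicate 4, Col6a3 (16.83 CPM) and Dpt (14.65 CPM) were lower and Lamc1 (336.7 CPM) was higher than in the other fl/fl libraries.

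The 3 genes of the fixed cell cycle list that were in the rows changed, in both directions. Mcm3 and Mcm6, subunits of the replicative helicase, rose by 15.3% and 15.1% to 438.9 ± 10.4 and 447.1 ± 4.52 CPM in KO (edgeR adjusted p = 3.68e-07 and 1.06e-07, n = 4 per group). Cenpf, a kinetochore protein of late cell cycle stages, fell by 11.5% to 164.1 ± 2.01 CPM (adjusted p = 3.38e-06). Of the 15 genes on the heat shock list only 2 were in the rows, and both fell, which describes this pair and not the list. Hspd1 fell by 16.4% from 1451 ± 44 to 1213 ± 19.6 CPM (adjusted p = 4.98e-10), and Hspe1, the cochaperonin of HSP60, fell by 16.3% from 263.5 ± 9.06 to 220.8 ± 8.17 CPM (adjusted p = 4.39e-08). The pair overlaps on opposite strands in the annotation used for symbols, so the counts of both are uncertain without strand. In fl/fl replicate 4, Hspd1 (1385 CPM) was lower and Mcm3 (402.9 CPM) higher than in the other fl/fl libraries.

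Among signalling and inflammatory genes, Ccl20, a chemokine of the senescence-associated secretion list, rose 3.27-fold at very low levels, from 24 reads over the 4 fl/fl libraries to 100 over the 4 KO libraries (log2 fold change 1.71, SE 0.40, edgeR adjusted p = 0.0017). Without fl/fl replicate 4 the log2 fold change of Ccl20 was 2.69. Atf3, a stress-induced transcription factor of the immediate early list, rose by 18.0% to 44.75 ± 1.6 CPM, and Nrp2, a co-receptor of the PDGF list, rose by 14.4% to 108.3 ± 2.9 CPM. Ptpn14, a phosphatase of the YAP target list, rose by 7.51%. The groups overlapped in both Nrp2 and Ptpn14. In fl/fl replicate 4, Nrp2 stood at 105.9 CPM, against 104.9 in KO replicate 4. Ptpn14 stood at 125.5 CPM there, against 121.4 in KO replicate 3. Nrp2 overlaps Gm29083 and Ptpn14 overlaps Gm26574 in the annotation used for symbols, so their counts are uncertain without strand. Cflar, the caspase-8 inhibitor cFLIP, fell by 8.68%. Cflar lost its call with upper-quartile scaling, library totals alone, forward-strand counts, DESeq2 or no filter, without fl/fl replicate 4 (adjusted p = 0.0769) and without KO replicate 4 (0.106), with a range of 0.0177 to 0.257. Ptpn14 lost it with forward-strand counts, without fl/fl replicate 1 (adjusted p = 0.0986), without KO replicate 1 (0.0595) and without KO replicate 2 (0.069), with a range of 1.07e-05 to 0.0986.

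The remaining 7 fixed-list genes did not pass the test. Caspase-8 (Casp8) stood at 54.91 ± 1.79 CPM in fl/fl and 53.62 ± 1.66 CPM in KO (log2 fold change -0.034, SE 0.038). Tgfb2, a TGF-beta ligand, stood at 7.737 ± 0.873 and 8.157 ± 0.977 CPM (0.066, SE 0.1). The respiratory chain genes Cox5b and Ndufb3 had log2 fold changes of 0.0051 (SE 0.032) and -0.033 (SE 0.047). Gli2, Batf3 and Cd34 had values of -0.27, 0.22 and 0.050. Batf3, a dendritic cell marker, lay near 3 CPM, and Cd34, on the portal fibroblast and mesothelium list, at 81.59 ± 3.14 CPM in fl/fl. The cholangiocyte gene Pkhd1 and the cytokine gene Il10 had 1 read each over the 8 libraries. Over the fixed-list genes together, 16 of 23 changed, 7 higher and 9 lower, and the count was also 16 when adjusted over the list alone. The lists other than the 16 with a kept gene, those of stellate cell identity, hepatocytes, macrophages and sinusoidal endothelium among them, gave no result.

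**Figure D3:**
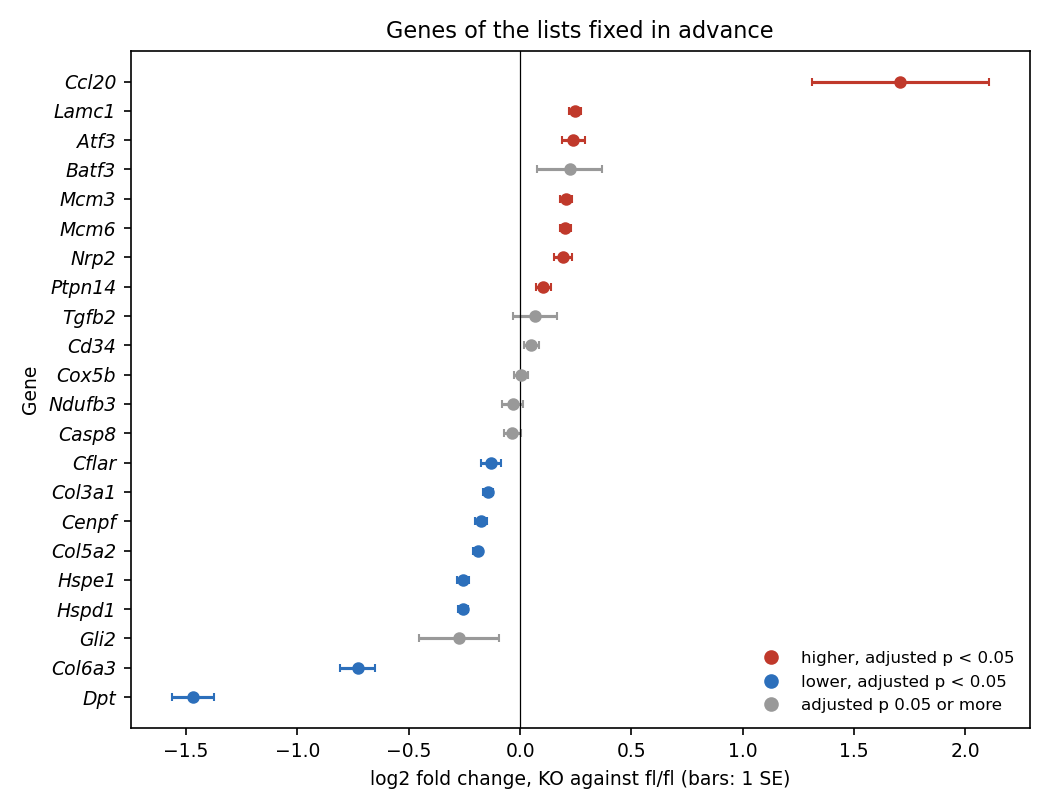
Log2 fold change of KO against fl/fl for 22 of the kept genes of the lists fixed in advance, with bars of 1 SE from the edgeR fit of 4 libraries per group. Red marks the 7 higher and blue 8 of the lower genes at adjusted p under 0.05, from Dpt at -1.47 to Ccl20 at 1.71.

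Shares of unmapped and unassigned reads differed between the groups as well. Unmapped reads made up 1.139% ± 0.07 of all reads in fl/fl and 1.517% ± 0.0556 in KO (SD, n = 4), and reads outside annotated features 4.32% ± 0.0187 and 4.052% ± 0.101. Each separated the groups fully (exact permutation p = 0.0286, the smallest possible, and 0.0667 after adjustment over 7 measures). The TMM factor separated the groups too (0.989 ± 0.00641 and 1.011 ± 0.0067, exact permutation p = 0.0286), and library totals overlapped (exact permutation p = 0.0571). Multimapping reads, at 3.912% ± 0.117 and 3.87% ± 0.0568, did not separate them (exact permutation p = 0.6). The labels give no batch or date, so no value within batches can be given, and a batch that follows the groups cannot be told apart from genotype. On the first principal component of the 420 genes (48.8% of the variance), KO libraries lay between 2.77 and 3.58 and fl/fl libraries between -6.20 and -0.88, with fl/fl replicate 4 nearest to KO. Without that library 191 genes changed, 154 of them among the 158.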

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

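The tests of thinned counts, a mixing share, a wrong label, the depth of a library, read shares and genes of other cell types were chosen only after the data had been examined; for thinning, the bound was set before its own value was known.

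In groups of 4, a library was picked out when its gap to the nearest other exceeded 0.829 of the group's range. Chance gives about 1 in 20 groups, 4.4 of the 88 tested. The groups tested are not independent, because a library that lies apart in many genes is counted for each of them. The chance number therefore gives no test of the number found. In total 12 were found, 8 of them in fl/fl replicate 4. In that library Klf7 stood at 26.61 CPM against 21.49 to 21.85 in the other fl/fl libraries (gap 0.93 of the range), Nrp2 at 105.9 against 90.26 to 91.93 (0.893), Mcm3 at 402.9 against 371.3 to 376.5 (0.835) and Ccl20 at 0.859 against 0.114 to 0.231 (0.842). Lower than in the others were Col6a3, at 16.83 against 22.28 to 22.86 CPM (0.904), Aox1, at 5.781 against 8.788 to 9.365 (0.839), Hspd1, at 1385 against 1469 to 1479 (0.894), and Gli2, at 1.66 against 2.486 to 2.521 (0.959). In fl/fl replicate 1, Cenpf stood at 190.8 against 183.4 to 183.8 CPM (0.946), Cd34 at 86.24 against 79.38 to 80.53 (0.832) and the library total at 19663030 reads against 17619387 to 17642249 (0.99). In KO replicate 1, Ccl20 stood at 1.473 against 0.971 to 0.975 CPM (0.993).

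The first pattern is the place of fl/fl replicate 4 between the groups. Over 166 genes, those of the 420 that were called without it and had a mean of at least 5 CPM, its levels lay 0.448 of the way from the other fl/fl libraries to KO (95% bootstrap interval 0.397 to 0.495), and 146 of the genes (88%) lay toward KO. A wrong label of the whole library is argued against by the upper end of that interval, 0.495, and its depth by a total only 0.026% from that of another fl/fl library. Knockout RNA or cells mixed in at 1 share for all genes stays open. The scatter left around that share was 1.53 per degree of freedom. It was 1.37 times the highest scatter of the other fl/fl libraries around no mixing and 1.67 times the highest around their own fitted shares. These ratios lie on either side of a limit of 1.5, which was set when the places of some genes had been seen. Each scatter was scaled by the biological coefficient of variation of the fit without that library. This was 1.75% for fl/fl replicate 4 and 2.54% to 2.64% for the other fl/fl libraries. The scales therefore differ, and the ratios cannot decide for or against mixing. A difference of this library in the biology of its cells was not tested and may also account for the pattern.

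The second pattern is the difference between the genotypes. Of the 35 splits of the libraries into 4 and 4, only the real one gave 158 genes (1 of 35). The highest other split gave 0 with edgeR (107 at an unadjusted p under 0.05, against 189). Each other split mixes the genotypes within its groups, which widens the spread and makes few calls likely. With 35 splits the share cannot fall below 1 of 35. The real split came first, but a chance division of these 8 libraries is not excluded. Nor is a chance difference between the animals or cultures behind them. Unequal depth is argued against because 89.2% of the 158 genes stayed changed in the same direction after thinning to equal totals. For RNA of hepatocytes in 1 group, 7 hepatocyte genes reached at most 0.662 CPM in any library (Serpinc1, antithrombin). These genes were picked after levels had been seen and without Aox1, which stood at 8.206 ± 1.64 CPM in fl/fl and 1.835 ± 0.291 in KO. The low levels therefore hold for these 7 genes, and hepatocyte RNA is not ruled out. RNA of leukocytes stays open too, since the dendritic cell gene Batf3 reached 3.78 CPM among 12 leukocyte genes (2.966 ± 0.355 CPM in fl/fl and 3.432 ± 0.399 in KO). A difference in library preparation cannot be told apart from genotype, since the unmapped share separates the groups (exact permutation p = 0.0286) and no batch is labelled; the genotype itself could not be checked on Arel1.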

How the results depend on the processing

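The library-totals, strand-column and thinning alternatives were chosen after seeing the data. The count of 158 changed genes stayed within 1.5 times under all other scalings, tests, filters and count columns (120 to 183) and with adjusted p under 0.01 (108), but was 8 with a 2-fold minimum (3 higher, 5 lower). Upper-quartile scaling gave 172 genes, 120 higher and 52 lower, and put the median log2 fold change of all genes at 0.055 (0.0034 with TMM); adjusted p under 0.01 left 48 higher. DESeq2 gave 132 genes, 131 of them shared with the 158, and limma voom 183, all 158 included. Upper-quartile scaling shared 129 of the 158, library totals alone 142, forward-strand counts 106 and reverse-strand counts 108, so the genes called changed more than their number. Leaving out 1 library gave 132 (without KO replicate 1) to 191 genes (without fl/fl replicate 4), 58 to 95 higher and 71 to 96 lower. The replicate block gave 150 genes (71 higher, 79 lower). Deviations of same-numbered libraries correlated at -0.164, 0.13, -0.11 and -0.04, and no fl/fl library correlated best with its own number. These values gave no sign of pairing by number, but so few correlations cannot exclude it. Of the 31 called named genes, 27 kept call and direction in all 19 alternatives that could test them, and Per2, Ap1s3, Ptpn14 and Cflar lost the call in at least 1. The signs that reversed belonged to genes not called: Casp8 at 0.016 with upper-quartile scaling and 0.063 with forward-strand counts, Ndufb3 at 0.018 with upper-quartile scaling and 0.058 with reverse-strand counts, Cox5b at -0.015 with forward-strand counts and -0.00084 after thinning, and, with 1 library left out, Tgfb2 (-0.011 to 0.126) and Cox5b (-0.014 to 0.030). Casp8 was called with reverse-strand counts (-0.14) and Cd34 with upper-quartile scaling (0.10). The cause of these differences was not tested. The Arel1 fold change, the counts of changed gene lists and the covariates from hepatocyte, macrophage and endothelial lists gave no value, because the rows hold no Arel1, no gene of those 3 fixed lists and fewer than 5 kept genes of each list. In simulation 48% of 1.1-fold changes were recovered, so changes of that size may be missed at this depth and spread.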

Other observations

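All gene groups and tests in this part were chosen after the data were seen. Of 8 ribosome assembly genes in the rows, 5 rose in KO and none fell: Nop58, a core protein of box C/D snoRNPs, by 15.7% to 375 ± 5.45 CPM, Rrp15 by 18.3% to 71.89 ± 1.46 CPM, Rrs1 by 15.8% to 102.3 ± 1.51 CPM, Wdr12 by 13.8% and Utp14b by 17.7% (SD, n = 4; edgeR adjusted p between 4.55e-06 and 0.00278). Utp14b lies within Acsl3 and Wdr12 overlaps Carf, so their counts are uncertain. The same holds for genes named below, among them Orc2 (overlaps Nif3l1), Nek2 (Gm38037), Sgo2a (Kctd18), Nsl1 (Gm38188), Ahctf1 (Kif28 and Gm10518) and Twist2 (Gm29100). Overlap was judged from the bounds of whole genes and not of exons. Ncl, Ddx18 and Nvl did not pass, with log2 fold changes of -0.046, 0.079 and -0.020. Of 10 DNA replication and repair genes, 5 rose and none fell, Mcm3, Mcm6, Ercc5, Orc2 and Exo1. Of 7 mitosis and centromere genes, 4 fell and none rose, Cenpf, Nek2 (by 12.9% to 125.1 ± 3.82 CPM), Cenpl (by 12.6%) and Sgo2a (by 11.4%). With upper-quartile scaling, 3 of these 7 fell and 2 rose (Nsl1 and Ahctf1), and with library totals alone 4 fell and 1 rose (Nsl1); in the ribosome assembly and replication groups no gene fell under any scaling. In several of these genes fl/fl replicate 4 lay toward KO, with Nop58 at 354.8 against 309 to 317.1 CPM in the other fl/fl libraries, Rrs1 at 96.9 against 81.62 to 88.8 CPM, Wdr12 at 87.11 against 82.73 to 83.67 CPM and Mcm6 at 407 against 378.1 to 388.9 CPM. Of 9 extracellular matrix genes, 4 fell (Dpt and the collagens Col3a1, Col5a2 and Col6a3) and 3 rose, among them the laminin chain gene Lamc1.

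Whether each group moved together relative to the other genes was tested with camera over 6 groups. Ribosome assembly (adjusted p = 0.0187, higher), replication and repair (0.0458, higher) and extracellular matrix (0.0458, lower) passed with the preset correlation, and none did with an estimated correlation (adjusted p = 0.315, 0.315 and 0.297). Mitosis genes (adjusted p = 0.0882, lower) and ubiquitin and Nedd8 enzymes (0.3) did not pass, and mitochondrial proteins did not pass either (0.807), with a median log2 fold change of 0.031, a mean of -0.011 and a camera direction of lower. Of 21 mitochondrial genes 2 rose and 2 fell, and of 17 ubiquitin and Nedd8 enzyme genes 2 rose and 1 fell. The groups were picked from genes whose changes had been seen and were tested on the same data, so these values give no support for a common movement of any group.

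The replication genes Mcm3 and Mcm6 lay near 380.5 and 388.6 CPM in fl/fl. Nuf2, a kinetochore gene in the rows of 6 libraries, stood at 132 to 141 CPM in the 4 fl/fl libraries and at 117 and 119 CPM in KO replicates 3 and 4. Rgs5, a pericyte gene on the stellate cell identity list, was in the rows of fl/fl replicates 2, 3 and 4 alone, with 12, 11 and 7 reads (0.684, 0.636 and 0.401 CPM). The rows of the other libraries end before Rgs5, so its level there is not known. The developmental homeobox genes En1 (24.86 ± 0.881 CPM in fl/fl and 23.99 ± 1.66 in KO) and Pax3 (11.54 ± 0.614 and 10.53 ± 0.59) were detected in all 8 libraries, and neither passed the test between groups (edgeR adjusted p = 0.511 and 0.199). Hlx and Twist2, looked up together with En1 and Pax3, stood at 9.54 ± 0.623 and 13.6 ± 0.957 CPM in fl/fl. In KO they stood at 9.97 ± 0.767 and 12.8 ± 1.34 CPM. None of these genes is on the stellate cell identity list. Whether the libraries hold freshly isolated stellate cells of separate animals is in question, and no test of this was run. The doubt rests on En1, Pax3, the replication genes and a biological coefficient of variation of 2.53% between libraries. Rgs5 adds to it only for fl/fl replicates 2, 3 and 4.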
